A study of Homo sapiens with 485 samples.

How the data were processed

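RNA from 55 human tumor cell lines of the NCI-60 panel was measured on the Affymetrix human genome array named by the platform's probe table. Lines had been exposed to 0, 1000 or 10000 nM lapatinib for 2, 6 or 24 h, with 1 array per line, dose and time. Per the labels' protocols, cells were grown in RPMI-1640 medium with fetal bovine serum and plated 24 h before the drug, dissolved in DMSO, was added. Total RNA was extracted with RNeasy columns, its quality was read on a LabChip GX, and it was labelled with biotin by a one-cycle kit on a liquid handling robot, per the labels' protocols. The deposited values are log2 intensities of 22277 probe sets that were already normalized between arrays. Neither the labels nor the file state the normalization method or the log base. Base 2 was read from the range, whose highest value of 14.10 lies under the limit of 16 that a 16-bit scan sets on that scale. The quartiles of single arrays lay between 3.90 and 4.12 and between 7.76 and 8.03. Arrays have no read depth, so the spread between cell lines sets the precision given with each value.

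Of the probe sets, 19070 carry 1 gene symbol, 1043 several and 2164 none. Array controls number 62. A gene was represented by the probe set with the highest mean among those with 1 symbol, which gave 11963 genes, 4310 of them with several probe sets. Of these, 11954 gene ids matched the reference gene table (assembly GRCh38.p14, used for names only) and 9 did not.

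The cell line was the replicate and the pairing. For each dose and time, the 0 nM array of a line was subtracted from its treated array of that time, and the mean difference was tested with limma 3.58.1 in R 4.3.3 (moderated t, intercept only). The same test compared 10000 with 1000 nM, the effects at 2 times, and 0 nM arrays at 2 times. Differences between the 7 tissues with at least 6 lines used limma's moderated F. The relation to baseline EGFR or ERBB2 used a slope over lines, with the baseline taken from the 0 nM arrays of the other times. P-values were adjusted by the method of Benjamini and Hochberg over all 11963 genes, with a threshold of 0.05, and a fold limit of 1.5 was counted in addition.

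The 24 gene lists were written before the data were examined and hold 352 genes, of which 305 are measured here and 47 have no probe set with 1 symbol. The lists are ERBB receptors and ligands, ERK pathway output, immediate early genes, FOXO targets, the ATF4 amino acid response, ER chaperones and the unfolded protein response, cholesterol synthesis, fatty acid synthesis, lysosome, G1/S and DNA replication, mitosis, p53 targets, NRF2 targets, aryl hydrocarbon receptor targets, heat shock proteins, interferon-stimulated genes, NF-kB and inflammatory genes, hypoxia and glycolysis, ribosome biogenesis, BH3-only genes, and melanocyte, epithelial, mesenchymal and haematopoietic markers. A list's score in a line is the mean difference of its members. Scores were tested by 2-sided sign-flip permutation with 100000 draws, adjusted over 144 tests, and by limma's camera with a preset correlation of 0.01 and with an estimated one. The sign flips act on whole lines, so they keep the correlation between members of a list. Camera asks a different question, whether a list changed more than the other genes. Differences of scores between doses and times were adjusted over 288 tests, and differences between tissues used a permutation F-test adjusted over 144. Correlations of the ERK pathway output score with baseline EGFR, ERBB2 and ERBB3 were adjusted over 18 relations.

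The comparisons, tests, gene lists and the rule for naming genes were set before the data were examined. Named are the 10 genes with the largest change in each direction at 10000 nM and 5 at 1000 nM, among those past the threshold with the same sign in at least 75 percent of lines; the 4 members of each list with the largest change past the threshold; EGFR, ERBB2, ERBB3 and ERBB4; and up to 5 per direction elsewhere. The text prints a part of these. SK-OV-3 and MDA-MB-468 were picked beforehand for their known amplifications.

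The tests below were tried on simulated data with 11963 genes, 50 of them changed per size. The correlations of the ERK score and the slope on baseline ERBB2 were not. Paired limma recovered 36, 50 and 44 percent of genes changed by 0.1 (log2) at 1000 nM after 2, 6 and 24 h and 48, 36 and 18 percent at 10000 nM. At 0.25 it recovered 100, 96 and 98 percent at 1000 nM and 98, 98 and 88 percent at 10000 nM. At 0.5 it recovered 100 percent in each but 98 at 10000 nM and 24 h. False calls among unchanged genes numbered 4, 8 and 8 at 1000 nM and 5, 4 and 5 at 10000 nM. For 10000 nM at 24 h, the tissue F-test, with melanoma lines shifted, recovered 0 percent at 0.1 and 0.25, 46 at 0.5 and 94 at 1. There the slope on baseline EGFR, with sizes per log2 unit of baseline, recovered 90 percent at 0.1 and 100 above, with 18 false calls. For the same comparison, sign flips called 0 of 24 lists at 0 and 0.05, 14 at 0.1 and 21 at 0.25, and the permutation F-test 0 at 0, 2 at 0.25, 19 at 0.5 and 23 at 1. There camera with an estimated correlation called 0 of 24 lists at 0, 17 at 0.1, 21 at 0.25 and 24 at 0.5, and with the preset one 8 at 0, 22 at 0.1, 23 at 0.25 and 24 at 0.5.

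The pairing was checked by correlating the arrays, and each was closest to another array of their own line. Alternatives were centring each array on its own median, the mean over probe sets, leaving out the genes of lowest mean level (under 4.65, leaving 7975), no replicate block, 1 fit over all arrays, the Wilcoxon signed-rank test, only lines with all 9 arrays, leaving out 3 lines of shared origin (MDA-MB-435, NCI-ADR-RES and SNB-19) or each tissue, tissue as a covariate, leaving out the 2 lines farthest from the median baseline, and the median of list members. The alternatives that use 3' to 5' ratios of control probe sets, and leaving out each line in turn for list scores, were added after the data were seen. Probe sets with several symbols or none were left out of the comparisons, and leukemia and prostate lines, 2 of each, out of the tests between tissues. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.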

Results

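The arrays measured 55 human tumor cell lines of the NCI-60 panel with and without exposure to lapatinib, an inhibitor of the kinase activity of the receptors EGFR and ERBB2. Each line had 1 array per dose and time, and 47 lines had all 9 arrays. There were 54, 54 and 55 arrays at 0 nM after 2, 6 and 24 h, 52, 52 and 55 at 1000 nM, and 54, 55 and 54 at 10000 nM. The lines came from lung (9), melanoma (9), kidney (8), ovary (7), breast (6), central nervous system (6), colon (6), leukemia (2) and prostate (2). The deposited values of single arrays had medians between 5.17 and 5.56, on a scale read as log2 from its range, and reached at most 14.10. The cell line was the replicate, and an effect is the treated array minus the 0 nM array of that line at that time. Errors are SDs over lines, and the number of lines limits the precision. The smallest p the permutations can give is 1.0e-05, so adjusted p-values of 4.2e-05 for list scores and 3.9e-05 for their differences are the smallest possible. An adjusted p given with an estimated correlation is that of camera, which sets a list against all other genes. It answers a different question from the sign flips, which act on whole lines and so keep the correlation between members.

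The first question was which genes lapatinib changed at each dose and time. At 1000 nM and 2 h the changed genes were all lower than at 0 nM. TIPARP, a target gene of the aryl hydrocarbon receptor, fell by 0.28 ± 0.18 on the log2 scale (SD, n = 52), in 48 of 52 lines (limma adjusted p = 2.89e-11). The transcriptional repressor gene HES1 fell by 0.28 ± 0.37 in 43 lines (adjusted p = 1.28e-03). Of 12 immediate early genes, which growth factors switch on within minutes, 4 fell and 8 did not pass the test, and 6 fell when adjusted over the list alone. These were JUNB (-0.26 ± 0.39, lower in 40 lines), IER2 (-0.23 ± 0.31, lower in 39), KLF10 (-0.23 ± 0.30, lower in 41) and JUN (-0.16 ± 0.23, lower in 41). The mean of the list fell by 0.16 ± 0.26 in 40 of 52 lines (permutation adjusted p = 4.2e-05).

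Among 17 genes that report the output of the ERK pathway, which lies downstream of EGFR and ERBB2, 3 fell at 1000 nM and 2 h and 8 fell when adjusted over the list alone. They were IER3 (-0.25 ± 0.30), the feedback inhibitor SPRY2 (-0.19 ± 0.29) and FOSL1 (-0.17 ± 0.26), and the list score fell by 0.10 ± 0.17 in 38 of 52 lines (adjusted p = 1.4e-04). HBEGF, which encodes an EGFR ligand, fell by 0.21 ± 0.37 in 41 lines (adjusted p = 0.0350), while EGFR, ERBB2, ERBB3 and ERBB4 had changes between 0.00 and 0.02 (adjusted p = 0.965 to 0.999). By limma, 22 of 11963 genes changed, 0 higher and 22 lower. Of 24 lists, 10 passed the permutation test, 1 higher (heat shock proteins, 0.04, in 42 lines, adjusted p = 1.4e-04) and 9 lower. Of these, ERBB receptors and ligands (-0.03, lower in 35 lines) and ribosome biogenesis (-0.02, lower in 36 lines) did not pass camera with an estimated correlation. Their camera adjusted p-values were 0.289 and 0.150. The sign-flip call of ribosome biogenesis was lost when any of 19 single lines was left out (-0.01 without OVCAR-4, adjusted p = 0.0747). The gene count was 7 without ovarian lines, 14 without renal lines and 3 in 1 fit over all arrays.

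At 1000 nM and 6 h, the mean score of ERK pathway output genes was lower than at 2 h. Targets of FOXO, transcription factors held back by AKT signalling, rose. EGR1 fell by 0.79 ± 1.16 (SD, n = 51; lower in 31 lines; limma adjusted p = 6.77e-04). Of the 17 ERK output genes, 9 fell and 13 fell when adjusted over the list alone. Among them were the ERK phosphatase gene DUSP6 (-0.58 ± 0.97, lower in 35 lines), PHLDA1 (-0.45 ± 0.64, lower in 37), SPRY4 (-0.43 ± 0.72, lower in 34) and DUSP5 (-0.41 ± 0.76, lower in 34). The score of the list fell by 0.25 ± 0.42 in 37 of 51 lines (adjusted p = 8.0e-05; adjusted p = 0.0618 with an estimated correlation). The median of the ERK score over lines was -0.06 both at 2 h and at 6 h, so the lower mean came from a part of the lines. FOXO targets rose by 0.09 ± 0.17 in 37 lines (adjusted p = 2.4e-04). Of 14 members 3 were higher, 5 when adjusted over the list alone. CCNG2, which encodes a cyclin that slows the cell cycle, rose by 0.47 ± 0.58 in 42 lines, CITED2 by 0.28 ± 0.38 in 40 and CDKN1B by 0.14 ± 0.32 in 36.

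Genes of ribosome biogenesis fell by 0.09 ± 0.11 at 1000 nM and 6 h in 38 of 51 lines (adjusted p = 4.2e-05). Of 12 members 5 were lower, 8 when adjusted over the list alone, led by RRS1 (-0.22 ± 0.26). Outside the lists, the methionine adenosyltransferase gene MAT2A fell by 0.27 ± 0.28 in 47 lines (adjusted p = 3.21e-06), and HBP1 and PNRC1 rose by 0.31 ± 0.44 and 0.31 ± 0.43. EGFR, ERBB2, ERBB3 and ERBB4 had changes of 0.09, 0.01, 0.10 and 0.05 that did not pass (adjusted p = 0.166 to 0.960). In all, 540 genes changed, 118 higher and 422 lower. With each array centred on its own median the split was 254 higher and 207 lower. Of 24 lists, 12 passed, 4 higher and 8 lower, and 3 of these held with an estimated correlation, namely FOXO targets, ER chaperones (0.02, higher in 34 lines, adjusted p = 0.00302) and ribosome biogenesis. The gene count was 230 without renal lines, 320 without lung lines and 253 in 1 fit over all arrays.

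After 24 h at 1000 nM, the list scores of cholesterol synthesis, fatty acid synthesis and lysosome rose and those of the cell cycle fell. Camera with an estimated correlation between genes did not call the cell cycle lists. HMGCS1 and LSS, enzymes of cholesterol synthesis, rose by 0.45 ± 0.47 (SD, n = 55; 45 of 55 lines; limma adjusted p = 1.33e-06) and 0.37 ± 0.34 (49 lines; adjusted p = 2.18e-07). Of 15 cholesterol synthesis genes, 14 rose, also when adjusted over the list alone, and the score rose by 0.23 ± 0.27 in 45 lines (adjusted p = 4.2e-05). Fatty acid synthesis rose by 0.14 ± 0.17 in 45 lines (adjusted p = 4.2e-05). Of 9 members 6 were higher by either adjustment (6 when adjusted over the list alone), led by SCD (0.29 ± 0.34) and FASN (0.22 ± 0.35). Lysosome genes rose by 0.09 ± 0.11 in 48 lines (adjusted p = 4.2e-05). Of 20 members 10 were higher and 1 lower, 13 and 1 when adjusted over the list alone, led by the protease gene CTSD (0.22 ± 0.29).

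EGR1 remained below the 0 nM level at 1000 nM and 24 h (-0.90 ± 1.16, lower in 44 of 55 lines, adjusted p = 4.77e-05). ERK output genes fell by 0.27 ± 0.49 in 37 lines (adjusted p = 1.1e-04; adjusted p = 0.130 with an estimated correlation). Of 17 members 13 were lower, 14 when adjusted over the list alone, among them DUSP6 (-0.62 ± 1.06) and ETV5 (-0.58 ± 1.12). Mitosis genes fell by 0.17 ± 0.38 in 44 lines (adjusted p = 8.0e-05; adjusted p = 0.225 with an estimated correlation). Of 22 members 20 were lower, 22 when adjusted over the list alone. Genes of G1/S and DNA replication fell by 0.17 ± 0.42 in 37 lines (adjusted p = 7.5e-04; adjusted p = 0.273 with an estimated correlation). Of 20 members 11 were lower, 17 when adjusted over the list alone. Among markers of cell types, the epithelial score was 0.06 ± 0.16, higher in 34 lines (adjusted p = 0.0116; adjusted p = 0.355 with an estimated correlation), with 1 of 8 members higher, also when adjusted over the list alone. The haematopoietic score was -0.04 ± 0.11, lower in 37 lines (adjusted p = 0.0240; adjusted p = 0.442 with an estimated correlation), and none of its 7 members passed by either adjustment. ERBB3 rose by 0.23 ± 0.57 in 34 lines (adjusted p = 0.0184), and EGFR (0.00, adjusted p = 0.997), ERBB2 (0.09, adjusted p = 0.228) and ERBB4 (0.06, adjusted p = 0.418) did not pass. By limma 2358 genes changed, 1128 higher and 1230 lower. With each array centred on its own median the split was 846 and 1535. Of 24 lists 16 passed, 8 higher and 8 lower, and cholesterol synthesis, fatty acid synthesis and lysosome held with an estimated correlation. The count was 1110 without renal, 1515 without lung and 1544 without ovarian lines.

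At 10000 nM and 2 h, DDIT3, the stress-induced transcription factor CHOP, rose by 0.49 ± 0.46 (SD, n = 54) in 48 of 54 lines (limma adjusted p = 8.05e-08). TXNIP, an inhibitor of glucose uptake and thioredoxin, fell by 0.95 ± 0.90 in 45 lines (adjusted p = 8.05e-08). KLF10 fell by 0.57 ± 0.44 in 49 lines, TIPARP by 0.46 ± 0.34 in 50, HES1 by 0.43 ± 0.54 in 42 and ID1 by 0.28 ± 0.35 in 44. CLK1, a kinase of splicing factors, rose by 0.40 ± 0.45 in 46 lines, CCNG2 by 0.38 ± 0.47 in 45 and KLF6 by 0.36 ± 0.38 in 46. Genes that ATF4 induces when amino acids run short rose by 0.10 ± 0.12 in 46 lines (adjusted p = 4.2e-05). Of 25 members 8 were higher; adjusted over the list alone, 9 were higher and 1 lower. FOXO targets rose by 0.04 ± 0.12 in 30 lines (adjusted p = 0.0481), a call undone by leaving out any of 30 single lines (0.03 without A498, adjusted p = 0.0837). Of 14 members 6 were higher and TXNIP lower, 7 and 2 when adjusted over the list alone.

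Genes of G1/S and DNA replication fell by 0.04 ± 0.05 in 46 of 54 lines at 10000 nM and 2 h (adjusted p = 4.2e-05). Of 20 members 4 were lower, 6 when adjusted over the list alone. Mitosis genes went the other way, by 0.03 ± 0.06, higher in 43 lines (permutation adjusted p = 0.00173). Camera with an estimated correlation did not call them. Of 22 members 3 were higher, 4 when adjusted over the list alone. Ribosome biogenesis fell by 0.05 ± 0.06 in 47 lines (adjusted p = 4.2e-05). Of 12 members 3 were lower, 4 when adjusted over the list alone. EGFR (-0.01), ERBB2 (-0.01), ERBB3 (0.02) and ERBB4 (-0.01) did not pass (adjusted p = 0.905 to 0.966). The ERK output score of -0.05 ± 0.20 did not pass (lower in 30 lines, adjusted p = 0.144), though 2 of its members, IER3 and FOSL1, fell, and when adjusted over the list alone 3 were lower and 1 higher. In all, 269 genes changed, 66 higher and 203 lower. Centred arrays gave 94 and 117. Of 24 lists 11 passed, 5 higher and 6 lower, and 4 held with an estimated correlation, namely the ATF4, FOXO, G1/S and ribosome biogenesis lists. The count was 113 in 1 fit over all arrays, 152 without renal lines, 170 without ovarian lines and 167 in lines with all 9 arrays.

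At 10000 nM and 6 h, every measured member of the ATF4 list rose, 25 of 25 over all genes and also when adjusted over the list alone. The list rose by 0.75 ± 0.39 in 54 of 54 lines (permutation adjusted p = 4.2e-05). DDIT3 rose by 1.73 ± 0.73 (SD, n = 54), 3.31-fold, in 54 lines (limma adjusted p = 1.51e-21). The glutathione-degrading enzyme gene CHAC1 rose by 1.63 ± 1.12 in 53 lines, TRIB3 by 1.23 ± 0.62 in 52, DDIT4 by 1.31 ± 1.21 in 48 and the stress cytokine gene GDF15 by 1.41 ± 1.24 in 48. TXNIP fell by 1.90 ± 1.37 in 49 lines (adjusted p = 3.95e-13).

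ER chaperone and unfolded protein response genes rose by 0.23 ± 0.18 in 53 lines at 10000 nM and 6 h (adjusted p = 4.2e-05; adjusted p = 0.0663 with an estimated correlation). Of 16 members 11 were higher, the same number when adjusted over the list alone, led by HERPUD1 (1.13 ± 0.54) and DNAJB9 (0.95 ± 0.67), while the chaperone gene HSPA5 rose by 0.21 ± 0.20. Lysosome genes rose by 0.18 ± 0.09 in 54 of 54 lines (adjusted p = 4.2e-05). Of 20 members 16 were higher, 18 when adjusted over the list alone, among them the autophagy receptor gene SQSTM1 (0.57 ± 0.38) and the cholesterol exporter gene NPC1 (0.45 ± 0.37). FOXO targets rose by 0.16 ± 0.21 in 43 lines (adjusted p = 4.2e-05). Of 14 members 9 were higher and 3 lower, 10 and 3 when adjusted over the list alone. CCNG2 rose by 1.30 ± 0.67 in 54 lines and the insulin receptor substrate gene IRS2 by 0.59 ± 0.46 in 49. NRF2 targets of the oxidative stress response rose by 0.24 ± 0.17 in 51 lines (adjusted p = 4.2e-05; adjusted p = 0.0528 with an estimated correlation). Of 11 members 4 were higher, 5 when adjusted over the list alone, led by SLC7A11 (1.07 ± 0.86) and HMOX1 (0.90 ± 0.90). The median over members was 0.07.

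Falls at 10000 nM and 6 h included the targets of the aryl hydrocarbon receptor, by 0.26 ± 0.23 in 44 lines (adjusted p = 4.2e-05; adjusted p = 0.0920 with an estimated correlation). Its members CYP1B1 (-0.67 ± 0.71), TIPARP (-0.48 ± 0.50) and CYP1A1 (-0.35 ± 0.67), 3 of 6, fell, also when adjusted over the list alone. Mitosis genes fell by 0.17 ± 0.15 in 47 lines (adjusted p = 4.2e-05; adjusted p = 0.0772 with an estimated correlation). Of 22 members 19 were lower and 1 higher, 20 and 1 when adjusted over the list alone, and AURKA fell by 0.45 ± 0.25 in 54 lines. Genes of G1/S and DNA replication fell by 0.14 ± 0.10 in 53 lines (adjusted p = 4.2e-05). Of 20 members 10 were lower and 1 higher, 13 and 1 when adjusted over the list alone, led by CCNE1 (-0.48 ± 0.37) and CDC25A (-0.42 ± 0.28). Ribosome biogenesis fell by 0.19 ± 0.12 in 53 lines (adjusted p = 4.2e-05). Of 12 members 11 were lower, the same number when adjusted over the list alone.

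The ERK output score at 10000 nM and 6 h was -0.13 ± 0.44 and did not pass (lower in 28 of 54 lines, adjusted p = 0.0620). Still, 6 of its 17 members fell, DUSP6 (-0.55 ± 0.97) and CCND1 (-0.38 ± 0.49) among them, and 1 rose, by either adjustment (6 and 1 when adjusted over the list alone). EGFR rose by 0.13 ± 0.30 in 37 lines (adjusted p = 9.19e-03), ERBB3 by 0.17 ± 0.46 in 35 (adjusted p = 0.0289) and ERBB4 by 0.12 ± 0.31 in 39 (adjusted p = 0.0226), and ERBB2 changed by 0.05 and did not pass (adjusted p = 0.383). In all, 3487 genes changed, 1382 higher and 2105 lower, 34 of them at least 1.5-fold up and 6 at least 1.5-fold down. Centred arrays gave 1993 and 1603. Of 24 lists 14 passed, 9 higher and 5 lower, and 5 held with an estimated correlation, namely the ATF4, FOXO, lysosome, G1/S and ribosome biogenesis lists. Means and medians over members of their mean change differed in sign for p53 targets (mean 0.07, adjusted p = 0.0108; median -0.04; adjusted p = 0.931 with an estimated correlation) and for hypoxia and glycolysis (mean 0.04, adjusted p = 0.0334; median -0.02; adjusted p = 0.981 with an estimated correlation). Leaving out any of 3 single lines undid the hypoxia call (0.03 without SF-268, adjusted p = 0.0508).

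**Figure D1:**
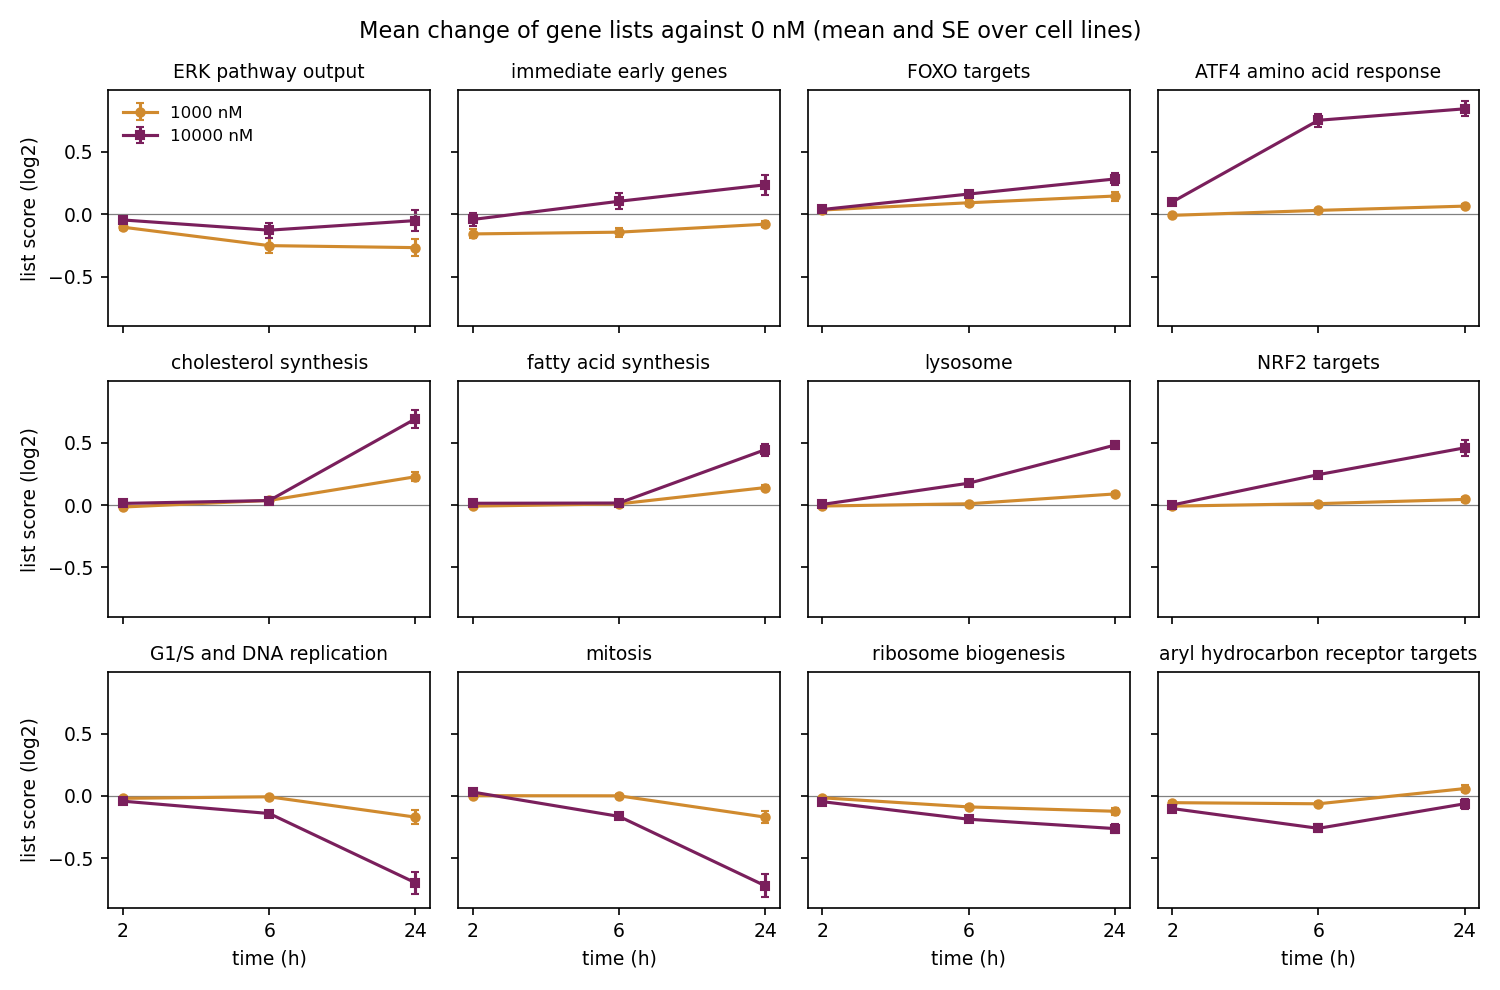
Mean list score (log2 against 0 nM of the same line and time; points are means over 51 to 55 cell lines and bars SEs) against time in hours, for 12 gene lists at 1000 nM (circles) and 10000 nM (squares). The ATF4 list reaches 0.75 at 6 h and 0.85 at 24 h at 10000 nM, and the mitosis list -0.72 at 24 h.

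After 24 h at 10000 nM, stress genes were still raised, genes of lipid synthesis and of the lysosome were higher, and genes of the cell cycle were lower. Camera with an estimated correlation, which sets a list against all other genes, called neither the lipid synthesis nor the cell cycle lists. GDF15 rose by 1.76 ± 1.45 (SD, n = 54) in 47 of 54 lines, the stress-induced regulator gene NUPR1 by 1.70 ± 1.45 in 48, DDIT3 by 1.43 ± 0.74 in 54, TRIB3 by 1.41 ± 0.73 in 53 and ASNS, which makes asparagine, by 1.30 ± 0.92 in 52 (limma adjusted p from 3.24e-18 to 3.99e-11). The ATF4 list rose by 0.85 ± 0.45 in 54 of 54 lines (adjusted p = 4.2e-05). Of 25 members 25 were higher by either adjustment (25 when adjusted over the list alone). INSIG1, HMGCS1, MSMO1 and LSS of cholesterol synthesis rose by 1.28 ± 0.78, 1.24 ± 0.85, 1.05 ± 0.75 and 1.01 ± 0.73, in 51, 53, 48 and 48 lines. The list rose by 0.69 ± 0.55 in 49 lines (adjusted p = 4.2e-05; adjusted p = 0.0920 with an estimated correlation). Of 15 members 15 were higher, also when adjusted over the list alone.

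Fatty acid synthesis genes rose by 0.44 ± 0.35 in 50 of 54 lines at 10000 nM and 24 h (adjusted p = 4.2e-05; adjusted p = 0.0721 with an estimated correlation). Of 9 members 9 were higher, also when adjusted over the list alone, led by SCD (0.85 ± 0.58) and FASN (0.75 ± 0.68). Lysosome genes rose by 0.48 ± 0.22 in 54 lines (adjusted p = 4.2e-05). Of 20 members 18 were higher, the same number when adjusted over the list alone. Among them the sialidase gene NEU1 rose by 1.17 ± 0.68 in 53 lines, GPNMB by 1.15 ± 1.55 in 45, SQSTM1 by 1.10 ± 0.59 in 54 and CTSD by 0.79 ± 0.52 in 51. FOXO targets rose by 0.28 ± 0.33 in 46 lines (adjusted p = 4.2e-05; adjusted p = 0.108 with an estimated correlation). Of 14 members 11 were higher and TXNIP lower, by either adjustment (11 and 1 when adjusted over the list alone). NRF2 targets rose by 0.46 ± 0.45 in 49 lines (adjusted p = 4.2e-05; adjusted p = 0.130 with an estimated correlation). Of 11 members 8 were higher, also when adjusted over the list alone, led by SLC7A11 (1.20 ± 1.02) and HMOX1 (1.20 ± 1.14).

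All 20 measured genes of G1/S and DNA replication and all 22 of mitosis fell at 10000 nM and 24 h, also when adjusted over the list alone. The replication list fell by 0.70 ± 0.63 in 51 of 54 lines and the mitosis list by 0.72 ± 0.67 in 53 (both adjusted p = 4.2e-05; both adjusted p = 0.130 with an estimated correlation). MCM10, a replication initiation factor, fell by 1.19 ± 1.06 in 54 lines, the cyclin gene CCNE2 by 1.07 ± 1.08 in 50, the ribonucleotide reductase gene RRM2 by 1.06 ± 0.86 in 54 and the mitotic kinase gene PLK1 by 0.86 ± 0.78 in 51. Ribosome biogenesis fell by 0.26 ± 0.25 in 49 lines (adjusted p = 4.2e-05; adjusted p = 0.137 with an estimated correlation). Of 12 members 11 were lower, also when adjusted over the list alone.

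Inflammatory NF-kB genes rose by 0.33 ± 0.46 in 43 of 54 lines at 10000 nM and 24 h (adjusted p = 4.2e-05; adjusted p = 0.199 with an estimated correlation). Of 13 members 10 were higher, 11 when adjusted over the list alone, led by CXCL8 (0.91 ± 1.73) and CXCL2 (0.68 ± 0.90). Interferon-stimulated genes rose by 0.33 ± 0.61 in 42 lines (adjusted p = 4.2e-05; adjusted p = 0.439 with an estimated correlation). Of 13 members 10 were higher, 12 when adjusted over the list alone. Immediate early genes rose by 0.24 ± 0.58 in 34 lines (adjusted p = 0.00688; adjusted p = 0.631 with an estimated correlation). Their median over lines was 0.06, with scores from -0.74 in NCI-H522 to 2.07 in MALME-3M, so the mean came largely from a part of the lines. Of 12 members 7 were higher and 1 lower, the same numbers when adjusted over the list alone, led by ATF3 (1.39 ± 1.12). p53 targets rose by 0.19 ± 0.25 in 39 lines (adjusted p = 4.2e-05; adjusted p = 0.480 with an estimated correlation). Of 12 members 5 were higher and 3 lower, also when adjusted over the list alone, and the median over members was 0.08. GDF15, named above among the stress genes with the largest rises, is 1 of these members. It and the cell cycle inhibitor gene CDKN1A (0.50 ± 0.57) rose and the repair gene DDB2 (-0.30 ± 0.46) fell. ER chaperone genes rose by 0.16 ± 0.24 in 43 lines (adjusted p = 4.2e-05; adjusted p = 0.49 with an estimated correlation). Of 16 members 8 were higher and 1 lower, 8 and 2 when adjusted over the list alone. Heat shock protein genes fell by 0.10 ± 0.21 in 39 lines (adjusted p = 0.00271; adjusted p = 0.442 with an estimated correlation). Of 9 members 5 were lower and 1 higher, the same numbers when adjusted over the list alone. The hypoxia and glycolysis list had a mean of 0.13 ± 0.22, higher in 39 lines (adjusted p = 5.4e-04; adjusted p = 0.931 with an estimated correlation), but a median over members of -0.02. NDRG1 (0.83 ± 0.68) and VEGFA (0.82 ± 0.79) rose and the glycolytic gene LDHA (-0.23 ± 0.21) fell.

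Among markers of cell types, the haematopoietic score was -0.06 ± 0.13 at 10000 nM and 24 h, lower in 37 of 54 lines (adjusted p = 0.00228; adjusted p = 0.715 with an estimated correlation). Of 7 members 2 were lower and 5 did not pass; adjusted over the list alone, 1 was higher and 2 lower. The mesenchymal score of -0.08 ± 0.28, lower in 34 lines, was at the threshold (adjusted p = 0.0486; adjusted p = 0.699 with an estimated correlation) and rested in part on KM12 (-1.66). Without that line it was -0.05 ± 0.17 and did not pass (adjusted p = 0.0882), and leaving out any of 35 single lines undid the call. Of its 8 members 1 was lower, also when adjusted over the list alone, and 7 did not pass. The epithelial (0.05, adjusted p = 0.130), melanocyte (0.02, adjusted p = 0.411) and BH3-only (0.07, adjusted p = 0.0610) scores did not pass, nor did ERBB receptors and ligands (-0.00, adjusted p = 0.980), aryl hydrocarbon receptor targets (-0.06, adjusted p = 0.161) or ERK output (-0.05 ± 0.64, adjusted p = 0.646). ERBB3 rose by 0.39 ± 0.84 in 35 lines (adjusted p = 2.66e-03) and NRG1, which encodes a ligand of ERBB3, fell by 0.28 ± 0.54 in 40 (adjusted p = 9.42e-04), while EGFR (0.07), ERBB2 (-0.01) and ERBB4 (0.03) did not pass (adjusted p = 0.416 to 0.921).

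In all, 4944 of 11963 genes changed at 10000 nM and 24 h, 2361 higher and 2583 lower, 117 at least 1.5-fold up and 132 at least 1.5-fold down. Of 24 lists 18 passed, 12 higher and 6 lower, and the ATF4 and lysosome lists held with an estimated correlation. On the same arrays the log2 difference between the 3' and 5' probe sets of beta-actin, a sign of RNA quality, was 0.12 ± 0.11 above that at 0 nM in 46 of 54 lines (adjusted p = 1.2e-04), beside the rises and falls of all of these groups. That of GAPDH differed by 0.02 ± 0.08 (adjusted p = 0.462). With these differences as covariates, an alternative chosen after seeing the data, 2904 genes passed. Without the pairing by cell line (no replicate block), the 6 counts from 1000 nM and 2 h to 10000 nM and 24 h were 0, 0, 0, 0, 81 and 754.

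**Figure D2:**
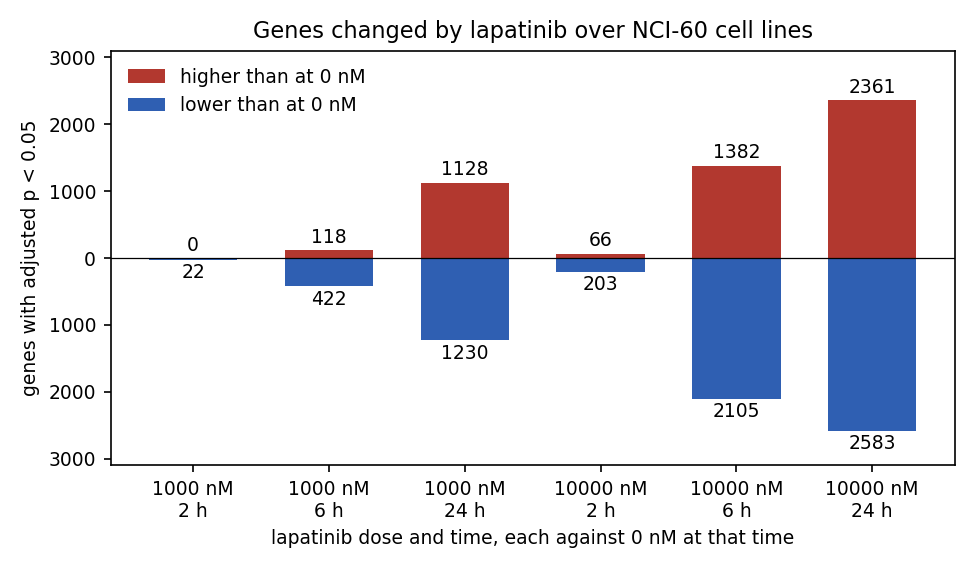
Number of genes (of 11963) with a limma adjusted p under 0.05, higher (red, above 0) or lower (blue, below 0) than at 0 nM, for each dose in nM and time in h. The counts reach 2361 higher and 2583 lower at 10000 nM and 24 h.

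The next question was where the doses differed, directly between the 10000 and 1000 nM arrays of each line. The ATF4 list was higher at 10000 nM by 0.11 ± 0.12 at 2 h (SD, n = 52; 44 of 52 lines), 0.72 ± 0.38 at 6 h (52 of 52) and 0.78 ± 0.43 at 24 h (54 of 54), each with adjusted p = 3.9e-05. TXNIP was lower at 10000 nM by 0.98, 1.81 and 0.99 on the log2 scale at 2, 6 and 24 h (-0.98 ± 0.81, -1.81 ± 1.25 and -0.99 ± 1.06; 44, 48 and 43 lines). At 24 h the lysosome list was higher by 0.39 ± 0.17 in 54 of 54 lines and cholesterol synthesis by 0.47 ± 0.50 in 44, and the replication and mitosis lists were lower (-0.52 ± 0.45 in 54 lines and -0.55 ± 0.48 in 53; each adjusted p = 3.9e-05). The aryl hydrocarbon receptor list was lower at 10000 nM by 0.20 at 6 h (-0.20 ± 0.17, 45 of 52 lines, adjusted p = 3.9e-05), led by CYP1B1 (-0.62 ± 0.57, 42 lines).

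ERK output genes, which fell at 1000 nM, were higher at 10000 nM than at 1000 nM at each time. The difference was 0.06 ± 0.11 at 2 h (37 of 52 lines, adjusted p = 0.00133), 0.11 ± 0.21 at 6 h (33 of 52, adjusted p = 9.6e-04) and 0.22 ± 0.31 at 24 h (40 of 54, adjusted p = 3.9e-05). Immediate early genes differed likewise, by 0.12 ± 0.22, 0.23 ± 0.37 and 0.32 ± 0.50 (36 of 52, 37 of 52 and 44 of 54 lines; adjusted p = 6.9e-04, 7.0e-05 and 3.9e-05). By limma 118 genes differed at 2 h (50 higher at 10000 nM, 68 lower), 2958 at 6 h (1302 and 1656) and 4133 at 24 h (1854 and 2279). Centred arrays gave 73 and 39 at 2 h. Of 24 lists, 10, 16 and 19 differed between the doses at 2, 6 and 24 h. Differences of lists were tested by sign-flip permutation only, over 288 tests together with those between times.

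How the effect changed with time was asked next, from the difference between the effects at 2 times in each line. At 10000 nM the ATF4 list gained 0.65 ± 0.36 from 2 to 6 h (SD, n = 53; 53 of 53 lines; adjusted p = 3.9e-05), while its further difference of 0.08 ± 0.39 to 24 h did not pass (adjusted p = 0.213). Cholesterol synthesis gained 0.65 ± 0.49 from 6 to 24 h in 48 of 53 lines (adjusted p = 3.9e-05) and did not pass from 2 to 6 h (0.03, adjusted p = 0.463). HMGCS1 gained 1.26 ± 0.77 from 6 to 24 h in 52 lines (limma adjusted p = 7.97e-14), and the effect on TXNIP came back by 0.99 ± 0.98 in 49 lines (adjusted p = 1.52e-08). The effect on mitosis genes moved down by 0.20 at first and then further (-0.20 ± 0.15 from 2 to 6 h in 48 lines, -0.56 ± 0.72 from 6 to 24 h in 47; each adjusted p = 3.9e-05). Interferon-stimulated genes gained 0.37 ± 0.63 from 6 to 24 h in 48 of 53 lines (adjusted p = 3.9e-05).

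At 1000 nM the mean effect on ERK output genes grew from 2 to 6 h (-0.16 ± 0.32, lower in 29 of 48 lines, adjusted p = 0.00209) and did not pass from 6 to 24 h (-0.03, adjusted p = 0.382). Cholesterol synthesis gained 0.19 ± 0.28 from 6 to 24 h in 40 of 51 lines (adjusted p = 7.0e-05), with HMGCS1 (0.40 ± 0.52) and LSS (0.38 ± 0.38) among the genes. The heat shock gene DNAJB1 moved down from 2 to 6 h (-0.27 ± 0.20, 44 of 48 lines, limma adjusted p = 7.06e-08). The numbers of genes whose effect differed at 1000 nM were 71 (6 against 2 h; 15 higher, 56 lower), 822 (24 against 6 h; 476 and 346) and 1067 (24 against 2 h; 496 and 571). Centred arrays gave 33 and 28, 246 and 922, and 370 and 705. At 10000 nM they were 1919 (849 and 1070; centred, 927 and 872), 3222 (1671 and 1551; centred, 1178 and 2155) and 3996 (1949 and 2047; with centred arrays 40.1 percent of the called genes were higher).

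The 0 nM arrays give the background of this time course. The labels give no batches and no batch term was used. Differences between times without drug therefore cannot be told apart from differences in processing by time. Between 2 and 24 h without drug, ATF3 fell by 1.26 ± 0.85 (SD, n = 54) in 51 of 54 lines (limma adjusted p = 3.02e-14) and the matrix protein gene CCN2 by 1.23 ± 0.91 in 52. DDIT4 rose by 1.43 ± 1.13 in 50 lines, and the zinc finger gene ZNF322 by 1.12 ± 0.43 in 54. Between 6 and 24 h the cold-inducible gene CIRBP fell by 0.87 ± 0.30 in 54 of 54 lines (adjusted p = 1.49e-25). Over 2 to 24 h the immediate early list fell by 0.39 ± 0.57 in 41 lines and the NF-kB list by 0.38 ± 0.43 in 45, and cholesterol synthesis rose by 0.27 ± 0.32 in 45 lines (each adjusted p = 3.9e-05). Mitosis genes rose by 0.25 ± 0.59 in 35 lines (adjusted p = 0.00133) and ribosome biogenesis fell by 0.17 ± 0.15 in 48 (adjusted p = 3.9e-05), while the lysosome list differed by 0.02 ± 0.12 and did not pass (adjusted p = 0.436). In all 3077 genes differed between 6 and 2 h (1676 higher, 1401 lower; centred, 1399 and 1600), 4111 between 24 and 6 h (2229 and 1882; centred, 1653 and 2850) and 3856 between 24 and 2 h (2223 and 1633; centred, 1530 and 2974).

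The next comparison asked whether tissues of origin differed in their response, over the 7 tissues with at least 6 lines. The 3 lines of shared origin (MDA-MB-435, NCI-ADR-RES and SNB-19) counted as separate lines in these tests. Leaving them out was tried only for the drug effects and list scores over all lines. EGR1 differed between tissues at 1000 nM and 2 h (limma F = 10.92, adjusted p = 1.68e-03), with a mean of -1.80 ± 0.82 in ovarian lines (SD, n = 7), -0.80 ± 0.60 in renal (n = 8) and -0.43 ± 0.77 in lung lines (n = 9). It was 0.13 ± 0.28 in melanoma (n = 8) and -0.00 ± 0.46 in colon lines (n = 6). At 6 h EGR1 was again -2.26 ± 0.73 in ovarian lines (n = 7) and 0.34 ± 0.20 in colon lines (n = 5; limma adjusted p = 0.0204). With the mean over probe sets 0 genes passed at 6 h by limma, and 9 of 100 groupings of the lines, the real one included, gave at least 1 gene, so chance is not excluded there. The kinase gene PLK3 differed too at 2 h (adjusted p = 0.0367; -0.37 ± 0.29 in 7 ovarian and 0.29 ± 0.24 in 8 melanoma lines), as did PROZ (adjusted p = 0.0303; 0.58 ± 0.27 in 6 colon lines). These were 3 genes at 2 h and 1 at 6 h. At 2 h 563 genes had an unadjusted p under 0.05, fewer than the 598 expected by chance. At 24 h limma called 0, with 1179 genes at an unadjusted p under 0.05, against 598 expected by chance.

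At 10000 nM and 24 h some genes differed between tissues by their change in melanoma lines and others by their change in renal lines. TRPM1, a channel gene of melanocytes, changed by 1.40 ± 0.87 in 8 melanoma lines, and its means in the other 6 tissues lay between -0.14 and 0.01 (limma F = 16.71, adjusted p = 3.21e-06). BEST1 changed by 1.33 ± 0.56 in melanoma lines (n = 8) and by -0.03 to 0.32 elsewhere (adjusted p = 1.23e-05). MYOF, a membrane repair gene, changed by -0.71 ± 0.27 in melanoma lines (n = 8) and by 0.55 ± 0.34 in renal lines (n = 8; adjusted p = 1.41e-04). HS1BP3 changed by 1.36 ± 0.45 in renal (n = 8) and 1.21 ± 0.31 in lung lines (n = 9) but 0.15 ± 0.27 in melanoma (n = 8) and 0.20 ± 0.52 in colon lines (n = 6; adjusted p = 1.23e-05). ETHE1, a mitochondrial sulfur enzyme gene, changed by 0.80 ± 0.31 in renal lines (n = 8; adjusted p = 9.95e-05). At 6 h the syntaxin gene STX3 changed by 1.36 ± 0.24 in 6 central nervous system lines and 0.26 ± 0.12 in 9 melanoma lines (adjusted p = 0.0221), and P2RX7 by 0.87 ± 0.49 in melanoma (n = 9; adjusted p = 9.86e-03).

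In all 88 genes differed between tissues at 10000 nM and 24 h and 13 at 6 h. At 2 h limma called 0, with 520 at an unadjusted p under 0.05, against 598 expected by chance. The count at 6 h was 27 without the genes of lowest mean level and 3 with centred arrays. Of 144 list tests between tissues, 7 passed by permutation F-test. With the median of list members instead of the mean, 2 of these 7 held, FOXO targets at 1000 nM and 2 h and immediate early genes at 1000 nM and 6 h. FOXO targets differed at 2 h at 1000 nM (F = 6.85, adjusted p = 0.00576; 0.15 ± 0.02 in renal lines, n = 8, and -0.03 ± 0.08 in melanoma lines, n = 8) and at 2 and 6 h at 10000 nM (permutation adjusted p = 0.0141 each). There they were 0.19 ± 0.10 in renal lines (n = 8) and -0.02 ± 0.09 in melanoma lines (n = 9) at 2 h, and 0.29 ± 0.25 in lung lines (n = 8) and -0.04 ± 0.16 in melanoma lines (n = 9) at 6 h. Immediate early genes differed at 1000 nM and 6 h (permutation adjusted p = 0.0110; -0.38 ± 0.16 in ovarian lines, n = 7, and 0.13 ± 0.07 in colon lines, n = 5) and at 24 h (permutation adjusted p = 0.0276; -0.31 ± 0.19 in ovarian lines, n = 7). Lysosome genes at 10000 nM and 24 h ranged from 0.71 ± 0.24 in central nervous system lines (n = 6) to 0.29 ± 0.08 in melanoma lines (n = 8; permutation adjusted p = 0.00792). p53 targets ranged from 0.49 ± 0.21 in colon lines (n = 6) to -0.02 ± 0.12 in melanoma lines (n = 8; permutation adjusted p = 0.0290).

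The last comparison set the response against the level of the drug's targets in each line, taken from the 0 nM arrays of the other times. Lines with more ERBB2 mRNA had lower ERK output scores. Pearson's r was -0.48, -0.43 and -0.47 at 1000 nM after 2, 6 and 24 h (51, 50 and 53 lines; permutation p = 6.2e-04, 0.00241 and 4.2e-04; adjusted p = 0.00516, 0.00868 and 0.00516 over 18 relations). It was -0.43, -0.44 and -0.33 at 10000 nM (53, 53 and 52 lines; permutation p = 0.00190, 8.6e-04 and 0.0167; adjusted p = 0.00855, 0.00516 and 0.0301). Spearman's rho lay between -0.39 and -0.50 (permutation p = 0.00489 to 2.3e-04; adjusted p = 0.0126 to 0.00252). Without the 2 lines farthest from the median ERBB2 level r was -0.40, -0.37 and -0.32 at 1000 nM and -0.36, -0.35 and -0.24 at 10000 nM. Then the adjusted p of the 24 h relations was 0.0637 and 0.157. Within tissues r was -0.32, -0.44 and -0.40 and then -0.40, -0.52 and -0.30 (adjusted p = 0.0742, 0.0171, 0.0261, 0.0171, 0.00126 and 0.0742).

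For EGFR, r with the ERK output score was -0.34, -0.35 and -0.37 at 1000 nM and -0.37, -0.30 and -0.23 at 10000 nM (permutation p = 0.0151, 0.0122, 0.00543, 0.00669, 0.0303 and 0.103; adjusted p = 0.0301, 0.0275, 0.0163, 0.0172, 0.0495 and 0.155), with rho from -0.15 to -0.43 (permutation p = 0.277 to 0.00222; adjusted p = 0.384 to 0.00666). Within tissues r lay between -0.08 and -0.20 and none held (adjusted p = 0.47 to 0.630); without the 2 farthest lines r lay between -0.20 and -0.35 and only the 24 h relation at 1000 nM held (adjusted p = 0.0418). ERBB3 showed no relation past the threshold (r from -0.14 to 0.10, permutation p = 0.340 to 0.948, adjusted p = 0.471 to 0.948; rho from -0.27 to 0.05, permutation p = 0.0499 to 0.862, adjusted p = 0.0748 to 0.862; r without 2 lines from -0.19 to 0.04, within tissues from -0.29 to -0.09, adjusted p = 0.256 to 0.588). SK-OV-3, an ovarian line known for amplified ERBB2, had ERK output scores of -0.44, -0.98 and -1.69 at 1000 nM after 2, 6 and 24 h, ranks 3, 5 and 2 from the lowest. MDA-MB-468, a breast line known for amplified EGFR, had -0.22, -0.86 and -1.37, ranks 12, 7 and 4. The medians over lines were -0.06 at each time.

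**Figure D3:**
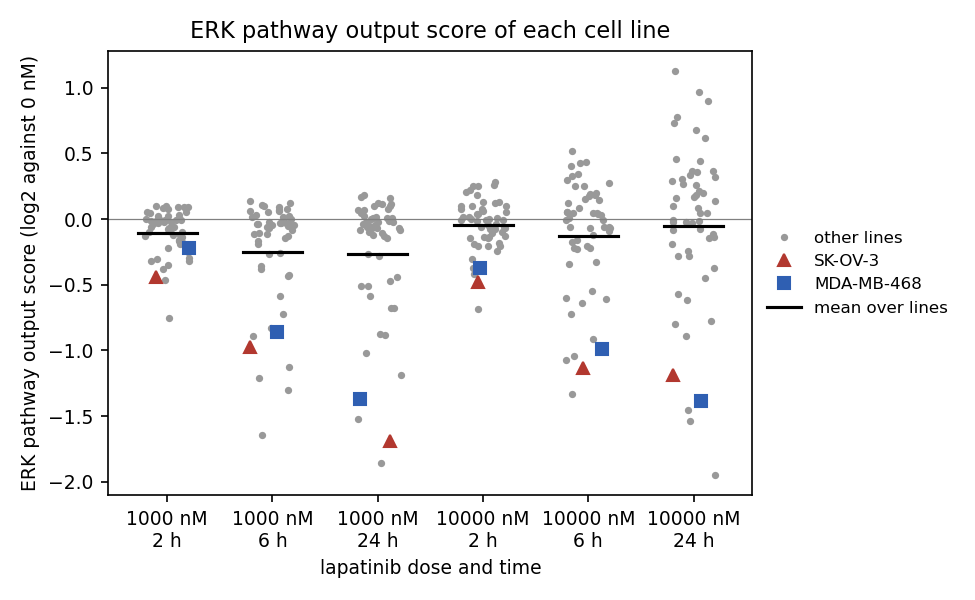
ERK pathway output score of each cell line (log2 against 0 nM of the same line and time) for each dose in nM and time in h; grey points are lines, the triangle SK-OV-3, the square MDA-MB-468, and bars means over 51 to 55 lines. At 24 h SK-OV-3 lies at -1.69 at 1000 nM and -1.19 at 10000 nM, against medians of -0.06 and 0.04.

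Single genes went with the baseline receptor levels in some comparisons. Each log2 unit of ERBB2 at 10000 nM and 6 h went with lower changes of DUSP6 (slope -0.38, SE 0.10, n = 53, limma adjusted p = 0.0369), DUSP4 (-0.32, SE 0.07, adjusted p = 0.0192) and PHLDA1 (-0.33, SE 0.08, adjusted p = 0.0314) and with higher changes of the ephrin gene EFNA1 (0.29, SE 0.07, adjusted p = 0.0307). At 1000 nM and 6 h it went with higher changes of CCNG2 (0.25, SE 0.06, n = 50, adjusted p = 0.0499) and DNAJB4 (0.22, SE 0.04, adjusted p = 1.66e-03). FOXO1, LPCAT3 and HTRA2 were the 3 genes that went with ERBB2 at 10000 nM and 24 h (0.28, 0.20 and 0.17; adjusted p = 9.21e-03, 0.0421 and 9.21e-03), but 5 of 100 permutations of the baseline levels, the real one included, gave at least as many, with 52 the highest other, so chance is not excluded there. Each log2 unit of baseline EGFR at 10000 nM and 24 h went with lower changes of EGR1 (-0.38, SE 0.08, n = 52, adjusted p = 6.59e-03), FOS (-0.21, SE 0.05, adjusted p = 0.0250) and ASNS (-0.19, SE 0.05, adjusted p = 0.0250) and with higher changes of PROS1 (0.18, SE 0.03, adjusted p = 2.22e-04). Most of these calls were lost in the alternatives, though each slope kept its sign. With tissue as a covariate only DUSP4 (-0.42, limma adjusted p = 0.0433) and FOXO1 (0.37, adjusted p = 0.0188) kept theirs. Of the lost ones, DUSP6 (-0.52) and PROS1 (0.19), for example, were at least as steep as before, and LPCAT3 (0.09) and EGR1 (-0.31) were flatter. Without the 2 lines farthest from the median baseline only EGR1 (-0.34, adjusted p = 0.0492) and PROS1 (0.16, adjusted p = 2.28e-03) kept theirs. There PHLDA1 (-0.41) was steeper and FOXO1 (0.27) about as steep, and DNAJB4 (0.15) and FOS (-0.14) were flatter. A lost call alone does not show that a relation runs through tissue or rests on 2 lines.

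For EGFR, limma called 7 genes at 10000 nM and 6 h (4 with positive slopes, 3 negative; centred, 4 and 5) and 177 at 24 h (112 and 65; centred, 96 and 129). It called 0 in the others, where 695, 763, 1754 and 657 genes had an unadjusted p under 0.05 at 1000 nM after 2, 6 and 24 h and at 10000 nM after 2 h. By chance 598 are expected in each. With tissue as a covariate both of the first counts were 0. For ERBB2 it called 38 genes at 1000 nM and 6 h (30 and 8; centred, 5 and 3), 86 at 10000 nM and 6 h (64 and 22; centred, 39 and 26) and 3 at 10000 nM and 24 h (3 and 0). It called 0 in the others, where 492, 1911 and 611 genes had an unadjusted p under 0.05 at 1000 nM after 2 and 24 h and at 10000 nM after 2 h. Here too 598 are expected by chance in each. With tissue as a covariate the 3 ERBB2 counts were 0, 14 and 1, and without the 2 farthest lines they were 1, 3 and 1.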

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

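The regroupings by chance in this part and the test of melanocyte genes were chosen after the results they measure were seen. The other tests of explanations were written before their own values were seen, but for patterns already picked from the results.

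The ERK pathway output genes were lower at 1000 nM than at 10000 nM at 24 h, by 0.22 ± 0.31 (SD, n = 54). Normalization between arrays with many changing genes is argued against, since the list's difference lay at percentile 100 of random lists matched on level. RNA quality as the whole cause is argued against too, since the difference at equal 3' to 5' ratios was 0.195 (SE 0.05). Whether the stress response at 10000 nM raised these genes cannot be told apart from other causes, because the dose differences of the ATF4 and ERK lists had r = 0.08 (permutation p = 0.567, rho = -0.03).

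Lysosome and cholesterol synthesis genes were both higher at 10000 nM at 24 h (0.48 and 0.69). With an estimated correlation between genes lysosome held (adjusted p = 0.00485) and cholesterol synthesis did not (adjusted p = 0.0920 with an estimated correlation). Both lists lay at percentile 100 of random lists matched on level. This likewise shows only a rise against other genes, so normalization stays open. RNA quality is argued against by changes of at least 5.63 SE at equal 3' to 5' ratios (for cholesterol synthesis 0.66, SE 0.118). A response shared by both groups may exist, but this stays open, since the correlation of their scores (r = 0.31, permutation p = 0.0238, adjusted p = 0.0476; rho = 0.28, permutation p = 0.0367, adjusted p = 0.0734) lay at percentile 91.61 of random lists. Without the 2 farthest lines r was 0.27 (p = 0.0520), and within tissues 0.48.

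TRPM1 and BEST1 were higher in melanoma lines at 10000 nM at 24 h. Both genes lie near the floor elsewhere: in 42 lines of other tissues TRPM1 was at 3.55 ± 0.16 and BEST1 at 3.95 ± 0.21 at 0 nM, where 15.8 percent of genes are lower than the higher of them, against 5.05 ± 1.43 and 5.62 ± 1.01 in 9 melanoma lines. The arrays might therefore miss small changes outside melanoma, but not every change, since BEST1 rose by 1.09 in the breast line T-47D. The melanocyte list had a mean of 0.21 (SE 0.088) in melanoma lines and was higher in 7 of 8. This exceeds 2 SE, but the exact sign-flip p of 0.0625 misses the threshold. MDA-MB-435, named above as a line of shared origin, counted as a separate line here, and leaving it out was not tried. A rise of melanocyte genes as a whole and a limit of detection elsewhere thus both stay open.

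A single line lay far from the others of its tissue in 10 of 147 groups tested, and chance does this in about 1 in 20. Among breast lines these were MDA-MB-468 for PROZ at 1000 nM and 2 h (-0.16), for EGR1 at 1000 nM and 6 h (-2.13) and for immediate early genes there (-0.32), T-47D for BEST1 (1.09) and MCF7 for MYOF (-0.97), both at 10000 nM and 24 h. The others were NCI-H460 among lung lines for CDC42EP1 (0.83) and OVCAR-8 among ovarian lines for PIBF1 (0.63) at 10000 nM and 6 h, SF-539 among central nervous system lines for immediate early genes at 1000 nM and 6 h (0.08), KM12 among colon lines for them at 24 h (-0.27), and COLO-205 among colon lines for lysosome genes at 10000 nM and 24 h (0.65).

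Effects differed between times by the test of the difference itself. At 1000 nM these were 71, 822 and 1067 genes and 5, 9 and 16 lists (6 against 2 h, 24 against 6 h, 24 against 2 h), and at 10000 nM 1919, 3222 and 3996 genes and 15, 12 and 18 lists. Between tissues 3 and 1 genes differed at 1000 nM after 2 and 6 h and 13 and 88 at 10000 nM after 6 and 24 h. Of the lists, FOXO targets (F = 6.85 at 1000 nM and 2 h, 5.13 and 4.94 at 10000 nM after 2 and 6 h), immediate early genes (F = 6.14 and 4.70 at 1000 nM after 6 and 24 h), lysosome (F = 6.39) and p53 targets (F = 4.53, both at 10000 nM and 24 h) differed.

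A signal was also seen in the 3151 probe sets with several symbols or none, array controls aside, which the report does not use. Of these, 1, 38 and 361 changed at 1000 nM after 2, 6 and 24 h and 26, 490 and 902 at 10000 nM (limma). The counts at an unadjusted p under 0.05 were 176, 328, 711, 370, 753 and 1157, against 158 expected by chance.

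Each count of genes was set against 100 regroupings, the real one included. For the drug, the signs of the differences were flipped at random, and chance is excluded in each comparison, with 1 of 100 as large: the real counts 22, 540, 2358, 269, 3487 and 4944 stand against highest others of 1, 1, 2, 1, 1 and 45. Between doses they were 118, 2958 and 4133 against 2, 3 and 1, with 1 of 100 each. Between times they were 71, 822 and 1067 against 1, 2 and 1 at 1000 nM and 1919, 3222 and 3996 against 2, 1 and 79 at 10000 nM, and for 0 nM arrays 3077, 4111 and 3856 against 8, 43 and 3, with 1 of 100 each.

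Tissue labels were permuted next. By this test chance is excluded for 13 genes at 10000 nM and 6 h and 88 at 24 h. Each was 1 of 100 (highest other 1). The 3 genes at 1000 nM and 2 h were also 1 of 100 (highest other 1). There 563 genes had an unadjusted p under 0.05, fewer than the 598 expected, so chance is not firmly excluded. The 3 lines of shared origin were permuted as separate lines, so these tests do not set aside their origin. Chance is not excluded for the 1 gene at 1000 nM and 6 h, which 9 of 100 matched (highest other 4). The counts of 0 at 1000 nM and 24 h and at 10000 nM and 2 h were matched by 100 of 100 (highest others 2 and 3).

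Baseline levels were permuted freely over lines, so these tests do not set aside a relation that runs through tissue. By them chance is excluded for the 7 and 177 genes that went with EGFR at 10000 nM after 6 and 24 h (1 of 100 each; highest others 2 and 14), but with tissue as a covariate both counts were 0. The 4 counts of 0 were matched by 100 of 100 (highest others 4, 2, 2 and 1). For ERBB2, chance is excluded by this test for 86 genes at 10000 nM and 6 h (1 of 100, highest other 7). With tissue as a covariate 14 genes were called, 5 of them among the 86, and without the 2 farthest lines 3, with 0 among the 86 by limma. For the 38 genes at 1000 nM and 6 h, 2 of 100 gave as many, but the highest other was 98 and 16 others called some. That count was 0 with tissue as a covariate, 1 without the 2 farthest lines and 8 with centred arrays, so chance is not firmly excluded there. Chance is not excluded for the 3 at 10000 nM and 24 h (5 of 100, highest other 52). The counts of 0 at 1000 nM after 2 and 24 h and at 10000 nM after 2 h were matched by 100 of 100 (highest others 145, 8 and 4). Some regroupings of ERBB2 called more genes than the real levels did, so limma can call genes here also at permuted levels. Of the other regroupings, 12 to 17 per comparison called genes for ERBB2, against 3 to 6 for EGFR. The cause was not tested.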

How the results depend on the processing

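The alternatives that use 3' to 5' ratios of control probe sets or leave out single lines were chosen after the data were seen; the others were set before the data were examined. Of the gene and list counts, 274 stayed within 1.5 times the reported count and 48 moved. The causes were not tested.

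Counts are given from 1000 nM and 2 h to 10000 nM and 24 h. With no replicate block the drug counts were 0, 0, 0, 0, 81 and 754 by limma. In 1 fit over all arrays they were 3 and 253 at 1000 nM after 2 and 6 h and 113 at 10000 nM and 2 h. Without ovarian lines they were 7 and 1544 at 1000 nM after 2 and 24 h and 170 at 10000 nM and 2 h. Without renal lines they were 14, 230 and 1110 at 1000 nM and 152 at 10000 nM and 2 h. Without lung lines they were 320 and 1515 at 1000 nM after 6 and 24 h, and with only lines that have all 9 arrays 167 at 10000 nM and 2 h. With 3' to 5' differences as covariates 2904 genes passed at 10000 nM and 24 h.

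Between tissues the count was 0 at 1000 nM and 6 h with the mean over probe sets, and at 10000 nM and 6 h it was 27 without the genes of lowest mean level and 3 with centred arrays. For EGFR, the mean over probe sets gave 1 at 1000 nM and 24 h and 2 and 93 at 10000 nM after 6 and 24 h, tissue as a covariate gave 2, 0 and 0 at 10000 nM, and at 10000 nM and 24 h the count was 280 without those genes and 67 without the 2 farthest lines. For ERBB2, the mean over probe sets gave 1, 290 and 77 at 1000 nM and 162 at 10000 nM and 6 h, with 196 higher and 94 lower at 1000 nM and 6 h. For ERBB2 the count was 90 at 1000 nM and 6 h and 5 at 10000 nM and 24 h without those genes, and 8 at 1000 nM and 6 h with centred arrays. Its 3 reported counts were 1, 3 and 1 without the 2 farthest lines and 0, 14 and 1 with tissue as a covariate.

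Of 81 list scores past the threshold, 25 also passed camera with an estimated correlation between genes. With the preset correlation 62 scores passed, 60 of them among the 81. Lists that differed between tissues numbered 3 with the median of members (7 as reported), 2 of them among the reported ones. Correlations of the ERK score past the threshold numbered 4 within tissues and 5 without the 2 farthest lines.

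For single named genes 6764 values kept their direction and side of the threshold, 842 fell short of it, 1 passed it and 1 reversed. The reversed one is RRP1B at 1000 nM and 6 h, 0.008 with the mean over probe sets. For list scores 2225 were the same, 171 weaker, 48 stronger and 4 reversed. At 10000 nM and 6 h p53 targets reversed with the median of members (-0.041) and with camera (adjusted p = 0.896 with the preset and 0.931 with the estimated correlation), and hypoxia and glycolysis reversed with the median of members (-0.01). This median is taken over members within each line and then averaged over lines, unlike the report's median over members of their mean change. With each line left out in turn, 75 to 84 list scores passed. For lists between tissues 11 values were the same, 5 weaker and 2 stronger, and for correlations 77 were the same and 13 weaker. Leaving out the 5 arrays with a beta-actin ratio above 3 moved no count by more than 1.5 times. Signal over background limits the tests of genes of low level, and leaving these out also means that fewer genes are tested.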

Other observations

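These values were chosen after they were seen, and no explanation is offered for them. At 10000 nM and 24 h the interferon-stimulated score was 3.01 in RPMI-8226, 2.96 in T-47D and 1.56 in OVCAR-4, against a median of 0.15 over lines. The NRF2 score was 2.74 in MCF7 and 1.41 in SW-620 (median 0.37). Cholesterol synthesis reached 1.89 in EKVX and 1.65 in PC-3 but was -0.57 in MOLT-4 and -0.50 in MCF7 (median 0.73). The ERK pathway output score was -1.95 in NCI-H322M, -1.54 in EKVX and -1.45 in CAKI-1 and 1.13 in a renal line (median 0.04).

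The log2 difference between 3' and 5' probe sets of beta-actin was highest on 5 arrays, which stayed in the comparisons: NCI-H226 at 1000 nM (3.21) and at 10000 nM (1.76) after 2 h, a renal line at 0 nM after 6 h (2.38), OVCAR-4 at 0 nM after 2 h (2.32) and COLO-205 at 0 nM after 2 h (1.64).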
